A study of Xenopus laevis with 46 samples.

How the data were processed

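RNA captured by a label for newly made RNA was measured in the animal pole (AP) and vegetal pole (VP) regions of Xenopus laevis blastulae. Embryos were kept at 22 °C in a dilute salt medium. At the 1-cell stage each received 10 nl of a 50 mM solution of 5-ethynyl uridine (EU), for a final concentration near 0.5 mM. EU is a uridine analog that is built into RNA while it is made and can be linked to biotin by a click reaction. The regions were dissected at 5, 6, 7, 8 and 9 hours post fertilisation (hpf). RNA carrying EU was linked to biotin, captured on streptavidin and made into libraries with removal of ribosomal RNA, per the labels.

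Per the submitters' processing notes, the authors quantified reads with Salmon 0.12.0 and normalized them with DESeq2, whose version is not given in the sources used here. The genome build and the annotation behind the table are not given in the sources used here either. The deposited table holds 50489 entries under 49233 distinct gene names and 46 libraries, and each value is a whole number in the unit score. Tests on the table showed such deposited scores to be normalized, rounded read counts: median-ratio factors recomputed over the 526 genes above 0 in all 46 libraries lay between 1.012 and 1.136. The design had assumed raw counts, so its fallback for normalized values was used. The depth in reads is unknown, and no interval for a fold change and no detection floor were computed. The 1256 entries that shared a name with an earlier entry were summed with it.

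Experiment 1 held 30 libraries in 10 groups of 3, with 1 library per clutch, region and time, and each clutch is a biological replicate. Experiment 2 held 16 libraries of 1 other clutch at 6 to 9 hpf, with 2 technical replicates per region and time. These were averaged, where the design had named sums, because the values were already normalized. No gene was tested in experiment 2. The labels do not state that a replicate number is the same clutch in both regions and at all times. Residual correlations between AP and VP libraries of a time were -0.024 to 0.103 for equal replicate numbers (median 0.028, 15 pairs) and -0.113 to 0.078 for unequal ones (median -0.013, 30 pairs). The replicate number was therefore an alternative block term and not part of the reported model. In what follows, a clutch of experiment 1 that is left out, blocked or compared means a replicate number.

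Genes with a value of at least 10 in at least 3 libraries of experiment 1 were tested, 19896 in all. Values were analysed as log2(value + 1) in limma 3.58.1 under R 4.3.3, with the data.table package at version 1.17.8, 1 coefficient per region and time, and moderated two-sided tests with a mean trend and robust settings. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with adjusted p under 0.05 were called. Counts at an unadjusted p under 0.05 are also given. If no gene differed, a share near 0.05 of the tested genes would reach it by chance. Every adjusted p given for a gene comes from this limma model unless another test is named. The contrasts were VP against AP at each time, each later time against 5 hpf within each region, and the interaction of region and time, which is the VP change from 5 hpf minus the AP change. VP against AP averaged over the 5 times was added after the data had been seen. A contrast of 9 against 5 hpf averaged over both regions was also fitted and is not reported.

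Log2 fold changes are given with standard errors (SE) and n = 3 libraries per group. Many genes, including those of ribosomal proteins, were listed at 0 in some libraries. For most of those genes the values of replicates 1, 2 and 3 are given in that order in place of a mean. No fold change is given against a group listed at 0 throughout, except the fitted interaction of mex3b.L. Medians over gene lists are of fitted changes, include such genes, and depend on the 1 added to each value. Onset was the first time at which a gene was called against 5 hpf with a log2 fold change of at least 1 that was kept at every later time.

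Lists of genes with known roles were fixed from general knowledge before the data were examined, as were the contrasts, the tests and the rule for naming genes, except where stated. A list of mitochondrially encoded genes had no measured member. Some lists share members, so their results are not independent. For example, grip2.L and pgat.L are in both the vegetally localized maternal and the germ plasm lists. Likewise ventx2.2.S is in the earliest zygotic, BMP and pluripotency lists. Lists were tested with limma's camera at a preset correlation of 0.01 and two-sided, with adjustment over lists within a contrast, and again with an estimated correlation and with fry. Members were also counted with p-values adjusted over the list alone. For the 4 contrasts at 9 hpf, the rule named up to 5 called genes per direction with the largest log2 fold change, a mean of at least 5 in the higher group and the same direction in all 3 clutches. The rule also named up to 2 called members per list, by smallest adjusted p, and a fixed set of marker genes. At earlier times it allowed markers and list members. Other genes named are stated to have been chosen after their values were seen. A gene that the rule named is not reported here.

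The model was tried on the libraries of experiment 1 with their group labels shuffled. Values of 200 of the 19896 genes were multiplied in AP at 9 hpf. Against AP at 5 hpf it called 0 of 50 genes multiplied by 4 and 2 of 50 by 16. It called 8 of 50 multiplied by 64, 21 of 50 by 256 and 0 unchanged genes. A listed 0 stayed at 0, and the median log2 change put in was 1.325, 2.65, 3.985 and 7.96. Shuffled groups mix regions and times, which can widen their spread, so these shares do not carry over to the real groups. Low counts of called genes still do not show that few genes differed. Names, gene types, neighbours and spans came from a reference table of the v10.1 assembly, which matched 17539 of the 19896 tested genes (88.2%). Its chromosome positions were used to order the genes when neighbours were counted.

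Alternatives covered the scaling, the filter, the added constant, the clutch block, summing of homeologs, the libraries in the model and leaving out each clutch. Scaling on the oocyte list, library weights, the number of genes above 0 as a covariate and leaving out 3 single libraries were added after the data had been seen. Tests that need raw counts, and scalings by trimmed means, were not run. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.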

Results

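Xenopus embryos begin to transcribe their own genome during the blastula stages, and the series asked when and where in the embryo new RNA appears. RNA was captured by a label for newly made RNA from AP and VP regions at 5, 6, 7, 8 and 9 hpf in 3 clutches (experiment 1, 30 libraries). It was also captured at 6 to 9 hpf in 1 further clutch with 2 technical replicates (experiment 2, 16 libraries). AP cells form ectoderm, and VP cells form endoderm and induce mesoderm. The depth in reads is unknown, and the deposited normalized read counts of a library summed to between 1783721 and 3273514. The number of genes above 0 varied between libraries of a group, from 4137 in VP at 8 hpf replicate 2 to 18199 in experiment 1 and from 4364 to 21140 in experiment 2. In AP it was 10970 ± 4118 (SD, n = 3) at 5 hpf and 15220 ± 2269 (SD, n = 3) at 9 hpf. In VP it was 12990 ± 5024 (SD, n = 3) and 12180 ± 2801 (SD, n = 3). X. laevis carries many genes as L and S copies (homeologs) and others in tandem, and how reads of near-identical copies were divided between them is not given in the sources used here.

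**Figure D1:**
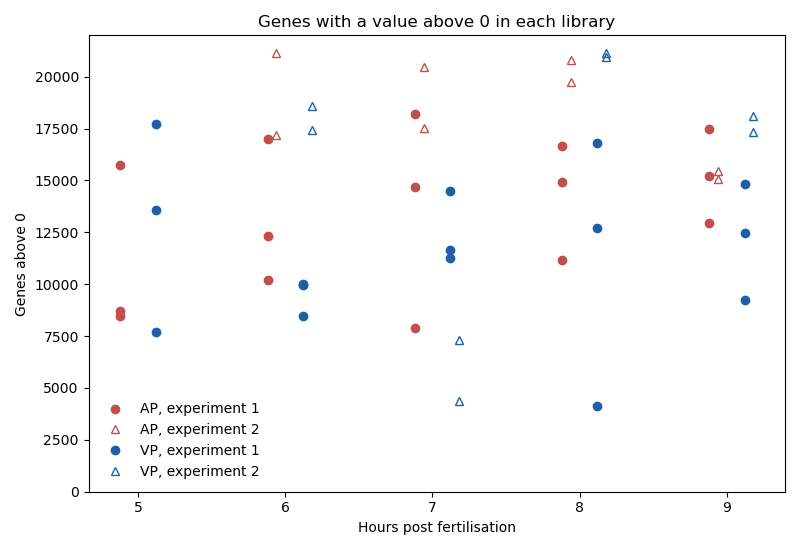
Number of genes with a value above 0 in each library (vertical axis) by hours post fertilisation (horizontal axis), region and experiment, each point 1 library. The libraries of a group spread widely, and VP at 8 hpf replicate 2 is the lowest with 4137 genes.

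VP was compared with AP at 5 hpf to find RNA that differed between the regions at the earliest time sampled. RNAs known to be stored at the vegetal pole of the egg were higher in VP, and whether they were newly made or carried over unlabelled stays open. The T-box factor vegt.L, a maternal activator of endoderm genes, had 1208, 983 and 2087 in VP and 96, 81 and 0 in AP (log2 fold change 6.08 ± 1.34 (SE), adjusted p = 0.0168). Its homeolog vegt.S was higher in VP by 5.83 ± 1.24 (SE) on the log2 scale (adjusted p = 0.0104). The germ plasm gene grip2.L had 2667, 1965 and 1460 in VP and 69, 0 and 0 in AP (log2 fold change 8.90 ± 2.00 (SE), adjusted p = 0.0189). Both copies of bicc1, an RNA-binding repressor of translation, were higher in VP, by 5.13 ± 1.18 (SE) for bicc1.L (adjusted p = 0.0271) and 7.53 ± 1.74 (SE) for bicc1.S (adjusted p = 0.029). In AP bicc1.L had 130, 94 and 3, and bicc1.S had 86, 0 and 0 against 763, 492 and 1456 in VP. In experiment 2 at 6 hpf bicc1.S had 65 and 84 in AP and 536 and 572 in VP, a smaller difference. The RNA helicase gene ddx25.L (8.19 ± 1.96 (SE), adjusted p = 0.0424) and the ubiquitin ligase gene trim36.L (8.50 ± 1.99 (SE), adjusted p = 0.0343) also passed. In AP they had 27, 5 and 0 and 35, 0 and 0. Fold changes against AP values at or near 0 depend on the 1 added to each value. The list of vegetally localized maternal RNAs as a whole was higher in VP (25 genes, median log2 fold change 6.08, camera adjusted p = 5.77e-45, with an estimated correlation 1.36e-05), with 7 called over all genes and 19 adjusted over the list alone. The germ plasm list followed (13 genes, median 5.03, camera adjusted p = 4.69e-10, with an estimated correlation 0.0149), with 2 and 7 genes. Among markers of early zygotic transcription, siamois (sia1.L) was at 0 in AP and at 0, 14 and 0 in VP, and mix1.L was at 0 in AP and at 0, 1 and 0 in VP.

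In all, 19 genes were higher in VP at 5 hpf and 0 were lower, among 19896 tested in limma. An unadjusted p under 0.05 was found for 854. If no gene differed, a share near 0.05 of the 19896 would have such a p, and 854 lies below that share. The 854 is therefore not a count of differing genes. Outside the naming rule and chosen after its values were seen, hwa.L, the gene of a maternal dorsal determinant, had 2891, 3440 and 3014 in VP and 72, 0 and 0 in AP (adjusted p = 0.000457). The count was 5, 24 and 6 without replicates 1, 2 and 3, 8 without VP at 5 hpf replicate 2 and 34 without VP at 8 hpf replicate 2.

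Between 6 and 8 hpf few genes were called between the regions. At 6 hpf 3 genes were higher in VP and 2 were lower, with 1266 at an unadjusted p under 0.05. The germ plasm gene pgat.L had 1772, 965 and 884 in VP and 0, 0 and 1 in AP (log2 fold change 9.83 ± 2.10 (SE), adjusted p = 0.0186). The other 4 genes were chosen after their values were seen: the endocytic adaptor gene ston1.S and the kinase gene wnk2.L were higher in VP, and the RNA-binding protein gene mex3b.L and the myosin phosphatase partner gene mprip.L were lower (each adjusted p = 0.0186). At 7 hpf 2 genes were higher in VP and 0 lower (692 at an unadjusted p under 0.05): grip2.L, with 2844, 1406 and 1964 in VP and 0 in each AP library (adjusted p = 0.000811), and hwa.L (adjusted p = 0.000811), the latter chosen after its values were seen. At 8 hpf limma called 0 genes, with 1349 at an unadjusted p under 0.05, and with the clutch as a block it called 3. Without replicates 1, 2 and 3 the counts were 0, 24 and 1 at 6 hpf, 0, 11 and 2 at 7 hpf and 0, 10 and 65 at 8 hpf, where 9 of the 10 were higher in VP and 58 of the 65 lower. Without VP at 8 hpf replicate 2 they were 27, 9 and 7. The 692 genes at an unadjusted p under 0.05 at 7 hpf lie below a share of 0.05 of the tested genes.

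VP was compared with AP at 9 hpf to find where the genes of the germ layers were transcribed. Genes of the endoderm network, of Nodal signalling and of the dorsal organizer were higher in VP, and single genes for a keratin and for E-cadherin were higher in AP. The endoderm homeobox gene mixer.S had 4257, 1167 and 2562 in VP and 1, 0 and 0 in AP (log2 fold change 10.86 ± 2.20 (SE), adjusted p = 0.00283). The endoderm factor gene gata6.S had 592, 111 and 376 in VP and was listed at 0 in AP (adjusted p = 0.00251). The Nodal ligand genes nodal5.2.L, with 1495, 654 and 680 in VP, and nodal6.L, with 558, 318 and 734, were listed at 0 in AP (adjusted p = 0.00787 and 0.0225). So was xenf.L, with 1539, 890 and 1423 in VP (adjusted p = 0.000898). The organizer homeobox gene gsc.S had 1078, 150 and 437 in VP and 0 in AP (adjusted p = 0.0115), while gsc.L missed the threshold (777, 209 and 919 against 23, 0 and 0, log2 fold change 7.53 ± 2.14 (SE), adjusted p = 0.0911). The secreted Wnt inhibitor gene frzb.S (1017, 179 and 220), the homeobox gene hhex.L (532, 76 and 403) and the mesoderm factor gene mespb.S (197, 153 and 88) were also at 0 in AP (adjusted p = 0.00114, 0.00322 and 0.00798). The spread is shared over all 10 groups, so a gene at 0 in most of them has it lowered. With only the groups compared in the model, gata6.S, nodal6.L, gsc.S, frzb.S, hhex.L and mespb.S were no longer called. Among maternal RNAs, grip2.L had 2052, 986 and 3264 in VP and 0 in AP (adjusted p = 0.000671), pgat.L had 952, 644 and 1297 against 0, 6 and 0 (adjusted p = 0.0134), and vegt.S was higher in VP by 4.93 ± 1.24 (SE) on the log2 scale (adjusted p = 0.0269).

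The genes named here as lower in VP at 9 hpf were listed at 0 in its 3 libraries. The keratin gene krt70.S had 52, 756 and 364 in AP (adjusted p = 0.014). The E-cadherin gene cdh1.S, for an adhesion molecule of epithelia, had 81, 321 and 87 (adjusted p = 0.0116). The transcription cofactor gene vgll4l.L had 55, 604 and 279 (adjusted p = 0.0162), and sowahb.S had 45, 201 and 247 (adjusted p = 0.0225). With only the groups compared in the model, none of these genes was still called. The epidermal markers grhl3.L (adjusted p = 0.956) and foxi4.2.S (adjusted p = 0.984) did not differ between the regions by this test.

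In all, 49 genes were higher in VP at 9 hpf and 26 lower, with 1431 at an unadjusted p under 0.05. With no filter on low values more genes were called and the split turned, with 103 higher and 130 lower. Of the 75 genes called with the filter, 71 remained called. Their directions could not change, since the fitted change of a gene does not depend on the filter. The endoderm list was higher in VP (28 genes, median log2 fold change 5.91, camera adjusted p = 3.68e-45, 5 called over all genes and 20 adjusted over the list alone), as were the organizer list (26 genes, 5.29, 4.21e-30, 3 and 18), the Nodal list (19 genes, 4.91, 9.94e-19, 2 and 12), the pan-mesoderm list (23 genes, 4.17, 5.1e-20, 1 and 9), the vegetally localized maternal list (25 genes, 4.17, 4.33e-31, 4 and 15), the germ plasm list (13 genes, 2.98, 3.86e-12, 3 and 5) and the list of earliest zygotic markers (41 genes, 1.69, 9.94e-19, 3 and 16). These 7 lists also passed with an estimated correlation (adjusted p from 0.000144 to 0.0125). The lists of histone and ribosomal protein genes, lower in VP, and of BMP and FGF genes, higher in VP, had 0 genes called over all genes and passed only with the preset correlation (with an estimated one, adjusted p = 0.297, 0.678, 0.349 and 0.401). Adjusted over the list alone, 5 histone genes were lower in VP and 1 BMP gene was higher. The ectoderm list did not pass (35 genes, median -1.33, camera adjusted p = 0.0628), with 1 lower gene over all genes and 2 adjusted over the list alone. The count was 12, 47 and 1 without replicates 1, 2 and 3, and 28 when at least 10 was asked of 6 libraries, with 24 of the 49 higher genes and 3 of the 26 lower genes still called. Under that filter 36 of the 75 genes could be tested. With only the groups compared in the model 16 of the 75 remained called (72 tested).

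**Figure D2:**
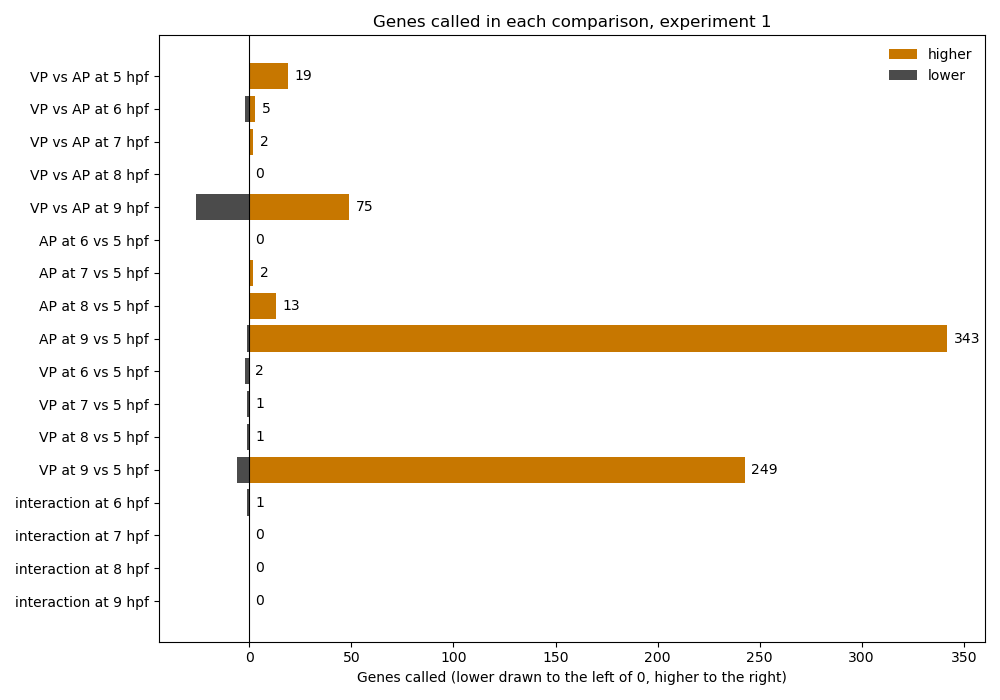
Number of genes called by limma (adjusted p under 0.05) in each comparison of experiment 1, with a bar to the right of 0 for higher genes, a bar to the left for lower genes and the total beside them. Called genes were few up to 8 hpf and reached 343 in AP, 249 in VP and 75 between the regions at 9 hpf.

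AP at later times was compared with AP at 5 hpf to follow the start of transcription in cells fated to ectoderm. Genes of pluripotency and of BMP response rose, and the first passed by 7 hpf. The POU factor gene pou5f3.2.S, an Oct4 relative, had 0, 0 and 1 at 5 hpf and 1947, 10360 and 7609 at 9 hpf (log2 fold change 12.05 ± 1.64 (SE), adjusted p = 3.13e-08), and had risen by 7 hpf (7.94 ± 1.64 (SE), adjusted p = 0.0392). Its homeolog pou5f3.2.L was above 0 at 5 hpf and rose by 4.32 ± 0.97 (SE) on the log2 scale by 9 hpf (adjusted p = 0.00637). Genes of the BMP-induced ventx homeobox family were listed at 0 at 5 hpf and rose: ventx2.2.S reached 1216, 5653 and 2625 at 9 hpf (adjusted p = 0.000224) and had risen by 8 hpf (adjusted p = 0.0231), ventx2.1.L reached 1329, 4491 and 3803 (adjusted p = 0.00259), and ventx2.1.S reached 1118, 4566 and 3345 (adjusted p = 0.000767). The epidermal factor genes foxi4.2.S, at 1176, 4772 and 4813, and grhl3.L, at 838, 3434 and 2016, were at 0 at 5 hpf (adjusted p = 0.00237 and 0.00636). So was the early zygotic gene gs17.L, at 498, 3733 and 2550 (adjusted p = 0.00659). The small nuclear RNA rnu2, part of the spliceosome, reached 901, 5082 and 5576 from 0 (adjusted p = 0.00141). The neural plate genes zic1.S, at 136, 1413 and 899, and lhx5.S, at 123, 769 and 312, rose from 0 (adjusted p = 0.0207 and 0.0241), whereas sox2.L did not pass (30, 41 and 42 against 0, adjusted p = 0.259).

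Some genes with vegetal roles rose in AP too. The endoderm factor gene sox17b.1.L reached 300, 1311 and 1019 and bix1.1.L reached 193, 693 and 140, both from 0 (adjusted p = 0.0109 and 0.0414). The cell cycle phosphatase gene cdc25b.L reached 250, 4143 and 1745 from 0 (adjusted p = 0.00868), and the ERK phosphatase gene dusp5.L and the immediate-early gene egr1.L, both targets of FGF signalling, also rose from 0 (adjusted p = 0.0314 and 0.0327). Histone genes were already high at 5 hpf: h3c14.L had 3325, 2517 and 4973, then 8344, 36217 and 44408 at 9 hpf (log2 fold change 2.78 ± 0.42 (SE), adjusted p = 1.16e-06), and h2ax.lS rose by 2.48 ± 0.43 (SE) (adjusted p = 5.66e-05). The only gene that fell was the extracellular matrix gene adamtsl1.S, from 12, 202 and 10 to 0 in each library (adjusted p = 0.0496), a fall that was lost in 11 of 17 other settings.

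In all, 342 genes rose in AP between 5 and 9 hpf and 1 fell, with 2043 at an unadjusted p under 0.05. The lists of earliest zygotic markers (median log2 fold change 5.42, camera adjusted p = 4e-16, 15 called over all genes and 22 adjusted over the list alone), pluripotency (3.75, 1.38e-15, 12 and 20) and BMP genes (3.53, 1.74e-11, 10 and 14) were higher at 9 hpf and held with an estimated correlation (adjusted p = 0.043, 0.0332 and 0.043). Other lists passed with the preset correlation only: neural (2.89, 7 and 16 genes), histones (3.17, 4 and 10), ectoderm (0.92, 10 and 11), FGF (4.96, 2 and 8), endoderm (3.58, 2 and 7), pan-mesoderm (2.13, 0 and 4), p53 targets (2.59, 2 and 4) and cell cycle (1.07, 4 and 8). The oocyte and egg list (camera adjusted p = 1.08e-06) and the replication factor list (median -0.87, camera adjusted p = 0.013) were lower, also with the preset correlation only (0.129 and 0.238 with an estimated one). With an estimated correlation the adjusted p of these lists lay between 0.0526 and 0.469. The count at 9 hpf was 62, 23 and 10 without replicates 1, 2 and 3. With only the groups compared in the model 91 of the 343 genes remained called (335 tested).

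At earlier times limma called 0 genes in AP at 6 hpf (686 at an unadjusted p under 0.05), 2 at 7 hpf (771) and 13 at 8 hpf (1342), and the called genes were higher than at 5 hpf. Besides pou5f3.2.S, the gene that passed at 7 hpf was ndst1.S, for a heparan sulfate enzyme (log2 fold change 5.70 ± 1.23 (SE), adjusted p = 0.0475), chosen after its values were seen. The 686 and 771 genes at an unadjusted p under 0.05 lie below a share of 0.05 of the tested genes. Without replicates 1, 2 and 3 the counts of called genes were 1, 0 and 0 at 7 hpf and 6, 0 and 6 at 8 hpf. Without AP at 8 hpf replicate 2 they were 0 and 1, and without VP at 8 hpf replicate 2 they were 1 and 22.

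VP at later times was compared with VP at 5 hpf to follow the start of transcription in cells fated to endoderm. Endoderm and mesoderm regulators rose from at or near 0 at 5 hpf. The homeobox gene mix1.L, an early target of Nodal signalling, went from 0, 1 and 0 to 6200, 3143 and 3800 (log2 fold change 11.70 ± 2.38 (SE), adjusted p = 0.00176). Of the related bix1 genes, bix1.3.L reached 5233, 2980 and 5117 (11.54 ± 2.41 (SE), adjusted p = 0.00231), bix1.3.S reached 5253, 2453 and 3053 (11.40 ± 2.41 (SE), adjusted p = 0.00261), and bix1.2.L reached 5407, 2096 and 5415 from 0 (adjusted p = 0.00176). The forkhead genes foxa4.S, at 2979, 1325 and 2061, and foxa4.L, at 2880, 1667 and 2115, rose from 0 (adjusted p = 0.000703 and 0.00149). The mesendoderm factor gene eomes.L reached 4570, 1519 and 1850, and snai1.S, a regulator of cell movement, reached 3871, 1769 and 2106, both from 0 (adjusted p = 0.00287 and 0.00288). The Nodal ligand gene nodal1.L reached 629, 401 and 970 from 0 (adjusted p = 0.00266). The endoderm factor gene sox17a.L went from 0, 10 and 0 to 2208, 1159 and 2080 (log2 fold change 9.62 ± 2.35 (SE), adjusted p = 0.0102). The organizer gene gsc.L reached 777, 209 and 919 from 0 (adjusted p = 0.00743), and fgf8.S, a growth factor gene, reached 1373, 484 and 1564 from 0 (adjusted p = 0.00885). The kinase gene cdk9.L, needed for elongation by RNA polymerase II, went from 143, 131 and 0 to 1431, 655 and 1084 (5.24 ± 1.36 (SE), adjusted p = 0.0182).

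Several markers missed the threshold in VP although they stood above 0 in most libraries. The dorsal gene sia1.L went from 0, 14 and 0 to 626, 491 and 0 (adjusted p = 0.464), the mesoderm gene tbxt.L from 0 to 88, 130 and 0 (adjusted p = 0.0705) and the head inducer gene cer1.S from 0 to 173, 0 and 104 (adjusted p = 0.12). The maternal genes vegt.L (log2 fold change 0.83 ± 1.34 (SE), adjusted p = 0.939) and gdf1.L, a TGF-beta ligand gene (-1.69 ± 2.20 (SE), adjusted p = 0.906), did not change by this test. Of 6 genes that fell, the zinc finger gene zfand4.L went from 1205, 609 and 657 to 6, 0 and 332 (-5.89 ± 1.32 (SE), adjusted p = 0.00448). The splicing regulator gene rbfox2.S (104, 121 and 461 at 5 hpf, adjusted p = 0.046), the death domain gene cradd.2.S (26, 34 and 333, adjusted p = 0.0347) and c14orf119.S (42, 18 and 195, adjusted p = 0.0357) were at 0 in each VP library at 9 hpf. The sphingolipid receptor gene s1pr5.S went from 80, 56 and 299 to 0, 1 and 0 (-6.47 ± 1.40 (SE), adjusted p = 0.00303).

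In all, 243 genes rose in VP between 5 and 9 hpf and 6 fell, with 1762 at an unadjusted p under 0.05. The number that fell was unstable, at 0, 39 and 2 without replicates 1, 2 and 3. It was 29 without VP at 8 hpf replicate 2 and 33 with library weights. The lists of earliest zygotic markers (median log2 fold change 8.11, camera adjusted p = 2.89e-57, 24 called over all genes and 37 adjusted over the list alone) and endoderm genes (8.86, 2.89e-57, 21 and 27) moved most. They were followed by the organizer (6.34, 12 and 23 genes), pan-mesoderm (5.80, 9 and 20), Nodal (5.60, 7 and 15), BMP (4.91, 13 and 18), FGF (3.97, 4 and 8), neural (3.23, 4 and 14) and pluripotency (2.25, 12 and 12) lists. These 9 lists also passed with an estimated correlation (adjusted p from 5.88e-05 to 0.0059). The ectoderm (0.33, 3 and 8 genes), cell cycle (0.36, 3 and 4) and histone (1.09, 1 and 4) lists, higher, and the oocyte (-1.09) and ribosomal protein (-1.38) lists, lower with 0 called, passed with the preset correlation only (adjusted p from 0.162 to 0.591 with an estimated one). The vegetally localized maternal list did not pass (median -0.79, camera adjusted p = 0.255).

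The count at 9 hpf was 0, 191 and 7 without replicates 1, 2 and 3 and 117 without VP at 5 hpf replicate 2. With only the groups compared in the model 113 of the 249 genes remained called (235 tested). At earlier times limma called 2 genes in VP at 6 hpf (981 at an unadjusted p under 0.05), 1 at 7 hpf (484) and 1 at 8 hpf (1265), and these were lower than at 5 hpf. The 981 and 484 genes at an unadjusted p under 0.05 lie below a share of 0.05 of the tested genes. With the clutch as a block 1 gene was higher and 1 lower at 8 hpf. The genes called without it were s1pr5.S at each time, at 0 in those 9 libraries (adjusted p = 0.0171, 0.0342 and 0.0342), and mex3b.L at 6 hpf, both chosen here after their values were seen. Without replicates 1, 2 and 3 the counts were 0, 9 and 0 at 6 hpf, 0, 1 and 0 at 7 hpf and 0, 0 and 55 at 8 hpf, where 54 of the 55 were lower. Without VP at 8 hpf replicate 2 they were 6, 0 and 0. Some other settings gave mostly rises at 8 hpf. There were 14 higher and 1 lower with no filter, 12 and 1 with 5 added before the logarithm, and 20 and 3 with experiment 2 added as a clutch.

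**Figure D3:**
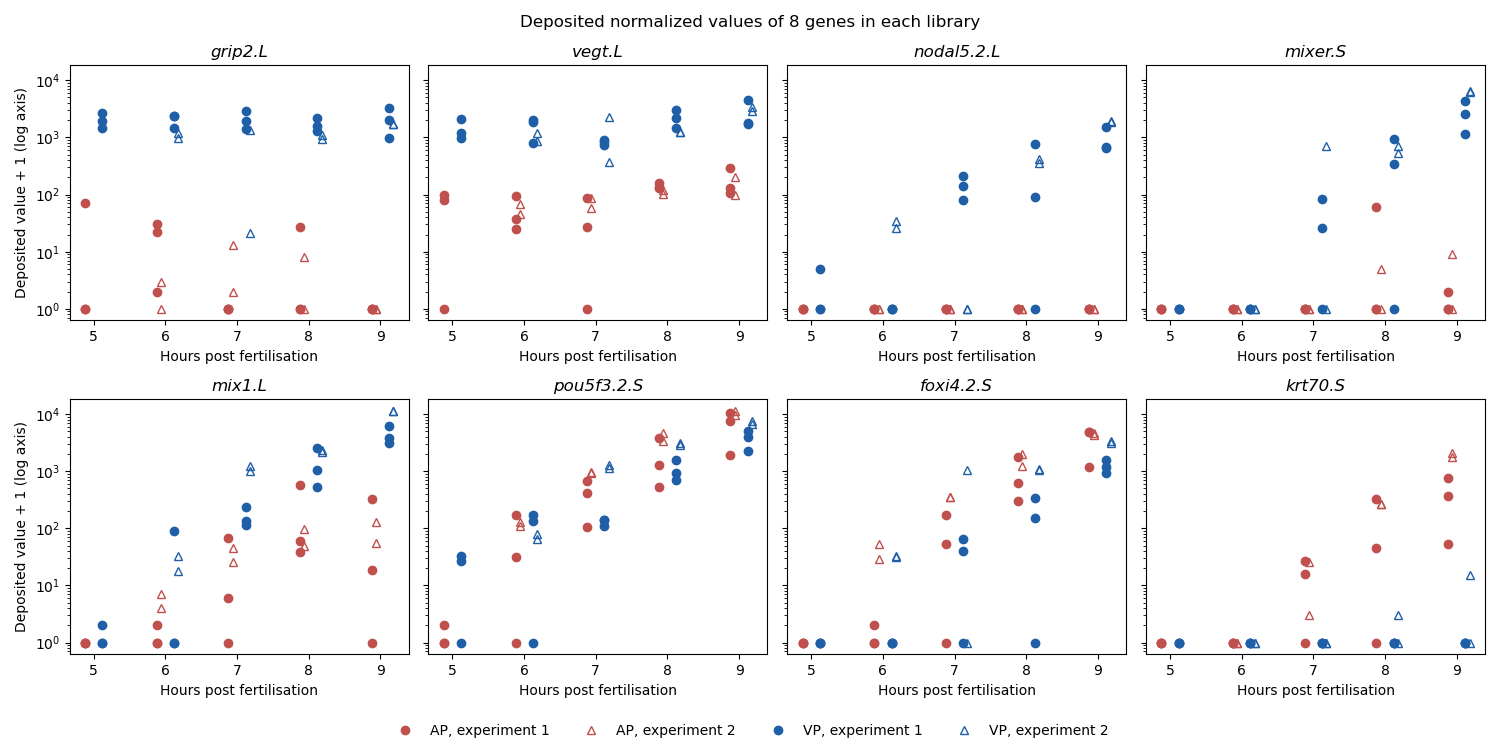
Deposited normalized values of 8 named genes in each library by hours post fertilisation (horizontal axis), with 1 added and on a logarithmic vertical axis, each point 1 library, filled for experiment 1 and open for experiment 2. Maternal vegt.L is higher in VP from 5 hpf, pou5f3.2.S rises in both regions, and mix1.L rises to 6200, 3143 and 3800 in VP at 9 hpf.

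The interaction of region and time asked whether the change since 5 hpf differed between the regions. At 6 hpf 1 gene passed, mex3b.L, for an RNA-binding protein: it had 92, 75 and 1117 in VP at 5 hpf and 0 in each VP library at 6 hpf, against 139, 2 and 0 and then 69, 366 and 188 in AP (adjusted p = 0.00148, chosen after its values were seen). The count at 6 hpf was 1 without replicates 1 and 2 and 0 without replicate 3. At 7, 8 and 9 hpf limma called 0 genes, with 593, 938 and 1042 at an unadjusted p under 0.05. Of these, 593 and 938 lie below a share of 0.05 of the tested genes, and 1042 lies above it. With p-values adjusted over the list alone, at 9 hpf 6 endoderm genes, 3 organizer genes and 1 pan-mesoderm gene rose more in VP, and 1 histone gene rose less. The endoderm (median difference in log2 fold change 5.27), Nodal (4.76), organizer (4.45) and pan-mesoderm (4.07) lists rose more in VP with camera (adjusted p = 6.83e-28, 5.13e-15, 8.59e-20 and 4.13e-13), and they held with an estimated correlation (adjusted p = 0.00488, 0.0127, 0.0127 and 0.0398).

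Of the genes that rose by 9 hpf, 342 in AP and 243 in VP, 78 rose in both, against 4.18 for independent lists (Fisher's exact test on genes, odds ratio 34.7, p = 1.98e-78). The 2 comparisons share no library, but they share the spread of each gene, which is estimated over all 10 groups. A gene with a low spread is thus favoured in both lists, which the 4.18 and the Fisher p do not allow for. Genes are also not independent replicates. A fitted change above 0 in the other region was found for 87.7% of the AP genes and 83.1% of the VP genes. Onset, counted at whichever time a gene first passed, came in AP at 7 hpf for 2 genes, at 8 hpf for 11 and at 9 hpf for 330, 343 in all, since a gene that passed earlier need not pass again at 9 hpf. In VP it came at 9 hpf for all 243. As the interaction at 7 and 8 hpf called 0 genes, an earlier onset in AP was not shown. Onset before 9 hpf in AP was found for between 0 and 5 genes when a clutch was left out, against 13.

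Experiment 2 gave the same sign for most called genes, least often for those lower in VP at 9 hpf, in a clutch that was not used to call genes. Between 6 and 9 hpf 336 of the 342 genes risen in AP and 242 of the 243 genes risen in VP were higher. Over all tested genes 42.1% in AP and 49.4% in VP were higher. Of the genes that differed at 9 hpf, 48 of 49 were higher in VP and 19 of 26 were lower. Over all tested genes 48.1% were higher in VP and 43.7% lower. Of the 19 genes higher in VP at 5 hpf, a time not sampled in experiment 2, 18 were higher there in the mean of 6 to 9 hpf, against 30.3% of all tested genes. These counts rest on 1 clutch.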

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

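The tests with an estimated correlation and with fry were planned, and mex3b.L was singled out only after the result was seen. The items below are differences between the regions in the change since 5 hpf. At 6 hpf the change of mex3b.L was lower in VP than in AP, with an interaction of -12.14 ± 2.21 (SE) on the log2 scale (limma adjusted p = 0.00148). This fitted value depends on the 1 added to each value, since it rests on 0 in each of 3 VP libraries at 6 hpf, while VP had 166, 227 and 105 at 7 hpf. In the clutch of experiment 2 mex3b.L had 116 and 62 in VP and 81 and 106 in AP at 6 hpf, so VP was not at 0 there. When the regions were permuted within times, 14 of 100 draws called at least the 1 gene called here and the highest other draw called 9, so chance was not excluded. For the interaction at 7, 8 and 9 hpf, with 0 genes called, all 100 draws gave as many, and the highest others were 11, 7 and 13.

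At 9 hpf 6 gene lists differed between the regions in their change since 5 hpf by camera at the preset correlation. The median interaction was 5.27 for the endoderm list, 4.76 for the Nodal list, 4.45 for the organizer list, 4.07 for the pan-mesoderm list, 1.92 for the list of earliest zygotic markers and 0.48 for the FGF list. With an estimated correlation the first 4 passed, and the earliest zygotic markers (adjusted p = 0.0861) and the FGF list (adjusted p = 0.708) did not. With fry the endoderm (adjusted p = 0.00546), Nodal (0.0401) and organizer (0.0401) lists passed, and the pan-mesoderm list (0.128) did not. The median over all tested genes was -0.87, so the list medians lay further above it than above 0 in the reported model. It depended on the setting, at 0.20 with the number of genes above 0 as a covariate. Without replicate 2 it was -0.13, and without VP at 5 hpf replicate 2 it was -0.43.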

How the results depend on the processing

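Scaling on the oocyte list, library weights, the covariate and the tests without VP at 5 hpf replicate 2, VP at 8 hpf replicate 2 or AP at 8 hpf replicate 2 were chosen only after the data had been seen, as was VP against AP averaged over 5 to 9 hpf, which called 141 genes. The other settings were planned. Results in this part are counts of genes called unless stated, and the cause of a shift was not tested except where fewer libraries or genes give it.

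With experiment 2 added as a further clutch and a clutch block, more genes passed: 30, 17, 6, 9 and 172 for VP against AP at 5, 6, 7, 8 and 9 hpf, 7, 64 and 607 for AP at 7, 8 and 9 hpf against 5 hpf, 3, 23 and 478 for VP at the same times, and 263 for the averaged contrast. With library weights, VP against AP gave 43, 38, 21 and 25 at 5 to 8 hpf, AP at 8 hpf 20, VP at 6, 7 and 8 hpf 8, 3 and 21, the interaction at 9 hpf 1 and the averaged contrast 260. With the number of genes above 0 as a covariate, VP against AP gave 17, 5, 4 and 134 at 6 to 9 hpf, AP at 7 hpf 4, and VP at 8 and 9 hpf 7 and 407.

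When at least 10 was asked of 6 libraries, which tested fewer genes, VP against AP gave 9, 4, 3 and 28 at 6 to 9 hpf, AP at 7 hpf 4, and VP at 6, 7 and 8 hpf 1, 0 and 0. Of the 75 genes called between the regions at 9 hpf, 36 could be tested under this filter and 27 remained called. This filter called 25 higher and 3 lower genes there. With no filter, VP against AP gave 5, 8 and 233 at 5, 8 and 9 hpf, the last with 103 higher and 130 lower against 49 and 26, AP at 7 and 9 hpf 0 and 555, VP at 6 and 8 hpf 1 and 15, and the interaction at 6, 7, 8 and 9 hpf 2, 1, 1 and 18. With homeologs summed, VP against AP gave 12, 6 and 8 at 6 to 8 hpf, AP at 7 hpf 0, VP at 6, 7 and 8 hpf 0, 0 and 3, and the interaction at 6 hpf 0.

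With 0.5 added before the logarithm, VP against AP at 5 and 6 hpf gave 8 and 2, AP at 7 and 8 hpf 0 and 6, and VP at 7 and 8 hpf 2 and 2. With 5 added, VP against AP gave 33, 19, 6, 13 and 164 at 5 to 9 hpf, AP at 8 hpf 22, and VP at 8 and 9 hpf 13 and 403. With only the groups compared in the model, VP against AP gave 32, 23, 53 and 23 at 5 to 8 hpf, AP at 6, 7 and 9 hpf 1, 1 and 149, VP at 6, 7 and 8 hpf 1, 3 and 5, and the interaction at 6, 7 and 9 hpf 0, 2 and 4. In that setting 16 of the 75 genes called between the regions at 9 hpf (72 tested), 91 of the 343 AP genes (335 tested) and 113 of the 249 VP genes (235 tested) remained called. Directions could not change there, since the fitted changes rest on the same libraries.

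With library totals VP against AP at 8 hpf gave 3, VP at 8 hpf 2 and onset before 9 hpf in VP 1. With median-ratio scaling VP at 8 hpf gave 2. With oocyte-list scaling VP against AP at 8 hpf gave 3, AP at 9 hpf 662, and VP at 7 and 8 hpf 0. With the clutch as a block VP against AP at 8 hpf gave 3, VP at 8 hpf 2 and onset before 9 hpf in VP 1, and no other count moved by more than 1.5 times. A minimum log2 fold change of 1 moved no count. The median log2 change of all tested genes was 0.41 in AP and -0.24 in VP from 5 to 9 hpf and -0.53 between the regions at 9 hpf. It was 0.27, -0.25 and -0.43 with library totals and 1.00, 0 and -0.78 with oocyte-list scaling. With the number of genes above 0 as a covariate it was -0.41, -0.07 and 0.05, so the first and last changed sign. Without replicate 2 it was 0.04, 0 and -0.38.

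Over the tests that left out a clutch or a single library, VP against AP ranged from 5 to 34, 0 to 27, 0 to 11, 0 to 65 and 1 to 90 at 5, 6, 7, 8 and 9 hpf, and from 68 to 197 averaged. AP at 7, 8 and 9 hpf ranged from 0 to 3, 0 to 22 and 10 to 433. VP at 6, 7, 8 and 9 hpf ranged from 0 to 9, 0 to 1, 0 to 55 and 0 to 296, and the interaction at 6 hpf from 0 to 1. With clutches alone left out, onset before and at 9 hpf ranged from 0 to 5 and 6 to 56 genes in AP and from 0 to 1 and 0 to 151 in VP. A clutch left out leaves 2 libraries per group, and counts went both down and up. Without replicates 1, 2 and 3, 46, 19 and 9 of the 343 AP genes, 0, 110 and 6 of the 249 VP genes and 7, 17 and 1 of the 75 genes between the regions remained called. Each gene kept its direction, which says little, since genes called from all 3 clutches have little room to reverse.

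With an estimated correlation, 7, 3 and 9 gene lists passed for VP against AP at 9 hpf, AP at 9 hpf and VP at 9 hpf, against 11, 13 and 14 with the preset one. With fry 7 and 9 passed for the first and last of these, and 3, against 6, for the interaction at 9 hpf. Of the 46 results for lists that passed, 45 with library totals and 46 with the clutch block kept their direction and their call. Named genes reversed in none of the up to 18 settings tried on each. This says little, since they were chosen as called and many also for the same direction in all 3 clutches. The most frequent losses of a call came from leaving out a clutch. With technical replicate 5 alone, the share of called genes with the same sign in experiment 2 was 95.3% for AP at 9 hpf, 95.6% for VP at 9 hpf and 94.3% averaged over times, against 98.3%, 99.2% and 98.6%. Settings that need raw counts, namely trimmed-mean scaling on all genes or on the oocyte list and tests in edgeR and DESeq2, were not run. The depth in reads is unknown. With shuffled groups 0 of 50 genes multiplied by 4 were called. Those groups mix regions and times, so the smallest change within reach is unknown.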

Other observations

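The contrast averaged over times, the tests of stored RNA, scaling and experiment 2, and those of homeologs, neighbours and transfer RNA were chosen only after the results were seen, whereas the splits of the samples and the test of gene span were planned. Averaged over 5 to 9 hpf, VP exceeded AP for 127 genes and was lower for 14. These counts were 200 and 63 with experiment 2 added as a further clutch, 205 and 55 with library weights and 134 and 27 without replicate 2. Of the vegetally localized maternal list 19 of 25 genes and of the germ plasm list 7 of 13 were higher in VP. They included grip2.L (log2 fold change 9.47 ± 0.89 (SE), adjusted p = 1.62e-18), dazl.L, a germ cell regulator of translation (7.97 ± 1.05, adjusted p = 6.02e-10), nanos1.L, a germ cell repressor of translation (7.59 ± 1.00, adjusted p = 5.51e-10), and gdf1.L (5.42 ± 0.98, adjusted p = 2.93e-05). The dorsal gene sia1.L was also higher in VP (3.80 ± 0.99, adjusted p = 0.0243), and the ectoderm genes tfap2c.S (-2.55 ± 0.61, adjusted p = 0.00895) and krt70.S, listed at 0 in each VP library of experiment 1 (adjusted p = 0.0401), were lower. The genes named for this contrast were chosen after their values were seen. The count was 69, 161 and 68 without replicates 1, 2 and 3. When the regions were permuted within times, 1 of 100 draws, the real one, called as many as 141 genes and the highest other called 44. That is the smallest share 100 draws can give, for a contrast added after the data had been seen.

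Vegetally localized maternal RNAs were higher in VP at 5 hpf. Unlabelled maternal RNA carried through the capture may account for them. A member of the oocyte and egg list was above 0 in 90.8% of the 6 libraries at 5 hpf, against 58.1% for random lists of tested genes (permutation test over 10000 random lists, p = 1e-04, the smallest they can give). The random lists were not matched on value. The oocyte kinase gene mos.L was above 0 in 29 of 30 libraries of experiment 1, cpeb1.L and wee2.L in all 30 and zar1.S in 15. These values go with stored RNA carried through the capture. How much of the vegetal RNA at 5 hpf it accounts for stays open. Transcription before 5 hpf was not tested.

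The genes that rose by 9 hpf were weighed against uneven detection and against scaling. In experiment 2, where the libraries list no more genes at 9 than at 6 hpf, 98.2% of the genes risen in AP were higher at 9 hpf, against 42.1% of all tested genes (exact binomial p = 3.94e-116). For the genes risen in VP it was 99.6% against 49.4% (exact binomial p = 1.16e-72), and genes are not independent replicates. Of 3 other scalings, median ratios repeat the method already applied and could change little. The oocyte list was itself lower at 9 hpf at the preset correlation, so scaling on it favours rises. These 2 scalings therefore decide nothing. With library totals 250 of 342 AP genes and 221 of 243 VP genes remained called. Uneven detection was argued against as the whole cause by experiment 2, and scaling by library totals alone. The division of reads between copies stays open.

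The 26 genes lower in VP at 9 hpf might follow from fewer genes above 0 in the VP libraries. In experiment 2, where VP at 9 hpf lists more genes than AP, 73.1% were lower in VP, against 43.7% of all tested genes (exact binomial p = 0.00231). With the number of genes above 0 as a covariate 25 of the 26 remained called, which also argues against uneven detection as the whole cause. When at least 10 was asked of 6 libraries 3 of the 26 remained, but only 36 of the 75 genes called in either direction could be tested. With only the groups compared in the model 16 of those 75 genes remained (72 tested). A gene listed at 0 in the other groups has its spread lowered by those libraries, which stays open as a part of the cause.

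Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. For VP against AP at 5, 6, 7, 8 and 9 hpf the real split called 19, 5, 2, 0 and 75 genes and the highest other 1, 1, 0, 0 and 8. For AP at 6, 7, 8 and 9 hpf against 5 hpf they were 0, 2, 13 and 343 against 1, 2, 2 and 4, and for VP 2, 1, 1 and 249 against 1, 0, 6 and 1. Splits as large, the real one included, numbered 1, 1, 1, 10 and 1 for the regions, 10, 2, 1 and 1 for AP and 1, 1, 4 and 1 for VP.

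A hypothesis was that both homeologs of a pair rise together. Both were called in 26 of 4958 pairs in AP, against 0.916 with shuffled partners, and in 37 in VP, against 0.825 (permutation test with 10000 shuffles, p = 1e-04 for each, the smallest they can give). Of pairs with 1 copy called, the partner had a fitted change above 0 in 84.5% in AP and 85.2% in VP, against 55.8% and 40.6% over all pairs. Shared control of the copies may explain this, and so could reads divided between near-identical copies.

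A further hypothesis was that genes risen in VP neighbour each other. In VP 24 adjacent pairs of tested genes both rose, against 2.2 with shuffled calls (permutation test with 10000 shuffles, p = 1e-04, the smallest they can give), and 14 of the pairs share a name stem, so tandem copies likely account for many. In AP the count was 20 against 3.78, but 75.4% of the risen genes had a place in the reference, under the 80% asked for, so that test is void.

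Genes risen in VP were short, with a median span of 5734 bp against 23218 bp for random lists matched on mean value (permutation test over 10000 random lists, p = 1e-04, the smallest they can give). Rapid cell cycles may favour short genes, which was not tested. In AP the median was 8143.5 bp, and the test is void for the same reason as above.

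A last hypothesis was that tRNA genes rise together. In AP 10 of 42 transfer RNA names rose by 9 hpf, 23.8% against 1.67% of other tested genes (Fisher's exact test, odds ratio 18.4, p = 1.78e-09, adjusted over gene types and regions 8.9e-09). In the same comparison 2 of 3 small nuclear RNA genes, 7 of 52 pseudogenes (13.5%, Fisher's exact test, adjusted p = 9.57e-05) and 9 of 196 long non-coding RNA genes (4.59%, adjusted p = 0.0116) rose in AP, against 1.39% of protein-coding genes. These values go against a rise particular to transfer RNA genes, but types other than transfer RNA came from the reference, which matched 78.4% of the genes risen in AP, under the 80% asked for, so they do not decide it. Chosen after its values were seen, trnar-ucg reached 624, 1394 and 2461 from 0 (limma adjusted p = 0.00859). In VP 2 of 42 rose, 4.76% against 1.21% (odds ratio 4.07, interval 0.474 to 15.8, exact p = 0.0931), which leaves a joint rise open there. The difference between the regions was not tested. These genes may begin transcription with the other genes that rose, although copies that share a name are listed together.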
